A study of Homo sapiens with 6 samples.

How the data were processed

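The data are 6 RNA-seq libraries of EoL-1 cells, 3 wild type and 3 ATF3 knockout, made with the Illumina Stranded mRNA Prep kit from polyadenylated RNA, per the labels. The authors deposited a Salmon transcript table for each library, which gives for 177456 Ensembl transcripts the estimated count of reads, the TPM, the length and the effective length, per the file headers. Salmon 1.6.0, FastQC 0.11.9 and the build hg38 are named in the submitters' processing notes. The library type, the bias options and the transcriptome release are not given in the sources used here. The design text calls the derivative a knockdown, while the labels of the samples call it a knockout made with CRISPR/Cas9, and the groups follow the labels.

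The deposited estimated counts need not be whole, and 93.0% of the values above 0 were not. They sum to between 26766103 and 30117281 reads per library. The deposited TPM values are scaled to a fixed total per library by the authors' quantification and were used as values alone, not in a test. The deposited effective lengths were the same in all 6 libraries and equalled the length less 250 bases for the transcripts over 3000 bases, so they hold no estimate of the fragment length or sequence bias of a single library. An offset made from them therefore follows shifts in the estimated mix of transcripts of a gene. Estimates of this kind can move reads between similar transcripts, and overlapping genes, paralogs and read-through genes named in the text are uncertain to that degree. Whether the quantification used the strand is not stated, so genes that overlap on opposite strands may share reads. Mitochondrial genes have nuclear copies, and RNASE2 and RNASE3 are paralogs.

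Transcripts were joined to genes by identifier, version ignored, with the GENCODE 29 annotation of GRCh38, which may not be the release the authors used. Of the transcripts, 167027 matched, 155671 of them with the same version, and 10429 had no gene. The transcripts without a gene held 3.59 to 3.82% of the reads, stayed out of library sizes and gene tests, and were tested by themselves. Estimated counts were summed over 35052 genes and rounded to whole numbers. Current symbols were found for 34878 genes in a table of gene names. Coordinates are those of the annotation, counted from 1.

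The main test was the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) on the group alone, over all 6 libraries, with TMM factors, the default filterByExpr filter with a minimum of 10 reads, and Benjamini-Hochberg adjustment at 0.05. It kept 13131 genes and had 4 residual degrees of freedom, with a biological coefficient of variation of 16.8%. CPM are TMM-scaled, and fold changes are knockout minus wild type on the log2 scale. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, adjusted over the 23 lists. Camera was repeated with an estimated correlation, which called 0 of the 23 lists where the preset value called 7 (5 higher, 2 lower). The fry test, which asks whether the genes of a list move on balance in a direction and compares them with no other genes, called 11 lists, and its mixed form, which asks whether genes change in either direction, called 17. Exact permutation tests were two-sided.

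The design, the alternatives, the lists and the naming rule were fixed before the data were examined. The rule names ATF3 with its transcripts, and then the 6 largest rises and 6 largest falls among protein-coding genes. These had to pass an adjusted p of 0.05, have every library of either group above every library of the other and reach a mean of 1 CPM in the higher group. It also names up to 3 called members per list with the smallest p, or the most abundant member where none was called. Other genes are said to be chosen after their values were seen, and a gene that the rule names is not reported here. The lists cover pro-angiogenic and anti-angiogenic factors, eosinophil genes, AP-1 and immediate-early genes, the integrated stress response, the unfolded protein response, hypoxia, type I interferon, NF-kB and inflammatory genes, MHC class II, cholesterol and fatty acid synthesis, NRF2 targets, p53 targets, cell cycle, adhesion molecules and mitochondrially encoded genes. Further lists hold markers of neutrophils, monocytes and macrophages, mast cells and basophils, megakaryocytes and erythroid cells, lymphocytes, and endothelium and stroma, and the genes around ATF3. Lists needed 3 tested genes. Several lists share members.

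The pipeline was tested on simulated data drawn from the means and library sizes of this comparison over 13131 genes, with 200 genes changed and a further list of 25 genes lowered 2-fold, and 12933 of the simulated genes passed the filter. It called 26.9% of the 67 genes changed 1.5-fold, 52.2% of the 67 changed 2-fold and 86.4% of the 66 changed 4-fold, and 9 of the 12714 unchanged genes that were tested. Camera called the lowered list and 0 of the 23 fixed lists. The simulated genes were drawn independently of each other, so this does not test camera where the genes of a list vary together. Fewer genes were changed in the simulation than the 2770 called in the data. The adjusted p depends on the share of changed genes, so the rates of detection need not hold for the real comparison. The alternatives were size factors of DESeq2 1.42.0, upper-quartile factors, the DESeq2 Wald test, limma-voom, no low-count filter, a mean of at least 1 CPM, the effective length offset, protein-coding genes alone, a replicate block, each library left out, and a test against a 1.5-fold change. Removal of a loess trend (span 0.3) on GC content or on transcript length, and the repeat of DESeq2 and limma-voom without wild-type replicate 1, were added after seeing the data. No pair of libraries agreed within sampling noise, since the median squared difference was at least 3.40 times that noise, and all 6 were kept. Tables were joined with Python 3.11.15 and pandas 2.3.3. Counting error is small beside the spread between libraries for abundant genes, and a gene at 0 reads in every library of a group is compatible with up to 3 reads over that group, or 0.0363 CPM over the knockout libraries.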

Results

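The libraries came from EoL-1, a human cell line established from an eosinophilic leukaemia and used as a model of eosinophils. Polyadenylated RNA was sequenced from 3 wild-type libraries and from 3 libraries of cells in which ATF3 had been targeted with CRISPR/Cas9, called knockout cells here after the sample labels. The series title places the data in a study of eosinophils and adipose angiogenesis, and the design implies a single comparison, ATF3 knockout against wild type. The libraries held between 26766103 and 30117281 estimated reads. The labels do not say whether replicates were separate cultures or clones, so the p-values measure only the spread between these samples.

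ATF3, a stress-induced transcription factor of the bZIP family, was lower in every knockout library than in every wild-type library, but its mRNA was still present. ATF3 (ENSG00000162772.16, chromosome 1, 212565334 to 212620777 on the plus strand of GRCh38) had 634, 462 and 632 estimated reads in wild-type replicates 1, 2 and 3, and 146, 229 and 132 in knockout replicates 1, 2 and 3. The means were 20.7 ± 3.88 CPM (SD, n = 3) in wild type and 6.16 ± 1.96 CPM (SD, n = 3) in knockout. ATF3 fell by 1.75 on the log2 scale (SE 0.25, edgeR adjusted p = 0.0098), a level 3.36-fold lower than in wild type. An exact two-sided permutation test of the 3 against 3 log2 CPM values gave p = 0.1, the smallest value that this design allows. Most of the difference lay in the protein-coding transcript ENST00000341491.9 (212608670 to 212620777), which held 389, 284 and 398 reads in wild type and 0, 95.3 and 45.4 in knockout. The protein-coding transcript ENST00000613954.4 (212608628 to 212620772) held 164, 138 and 136 reads in wild type and 104, 49.1 and 43.1 in knockout. Both transcripts span nearly the same bases, so the division of reads between them is uncertain. The retained-intron transcript ENST00000465155.5 overlapped between the groups, with 46.2, 26.8 and 54.7 reads in wild type and 29.9, 56.8 and 33.7 in knockout. The labels do not give the position of the edit, so a fall in mRNA does not show whether the remaining transcripts carry it. As ATF3 is stress-induced, its lower mRNA alone also cannot tell the edit from a difference in the state of the cultures. Without wild-type replicate 1 the log2 fold change was -1.68 with an adjusted p of 0.0527.

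Beyond ATF3, ATF5, TRIB3, SLC7A11 and SLC7A5 of the integrated stress response list fell in the knockout libraries. RNASE2 and RNASE3 of the eosinophil list, MS4A3, MPO and S100A8 of the neutrophil and granule list, and the cell cycle inhibitor CDKN1A rose. Among angiogenic factors, VEGFA and ANGPT1 fell, and MMP9 and ADM rose. Of 13131 genes tested, 2770 (21.1%) passed an edgeR adjusted p of 0.05, with 1494 higher and 1276 lower in knockout. Fitted changes of more than 2-fold were found for 217 of the higher and 129 of the lower genes, while a test against a 1.5-fold change called 10 higher and 7 lower genes. In 43.6% of the tested genes every library of either group lay above every library of the other, against 10% by chance for 3 against 3.

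The count of called genes differed with the library left out, and fell most without wild-type replicate 1. Without that library the smallest edgeR adjusted p was 0.0503, so no gene passed and every gene described as changed here lost its call. At that setting 3496 genes had an unadjusted p under 0.05, DESeq2 called 1073 higher and 963 lower, and limma-voom called 0 higher and 5 lower. Leaving out wild-type replicate 3 left 210 higher and 148 lower genes, leaving out knockout replicate 1 left 741 and 665, and leaving out knockout replicate 2 left 929 and 792. It stayed near the full count without wild-type replicate 2 (1342 higher and 1131 lower) and without knockout replicate 3 (1370 and 1388). Of the genes followed singly through the alternatives, 53 lost their call without wild-type replicate 3, 26 without knockout replicate 1, 22 without knockout replicate 2, 10 without wild-type replicate 2 and 6 without knockout replicate 3. All 2770 called genes kept the sign of their fold change in each of the fits without a library. With each gene's average effective length as an offset, 722 genes were higher and 661 lower, and 22 of the genes named in the text lost their call with the same sign. The largest adjusted p-values among these were those of ADAM32 (0.69), PRPF8 (0.228), MVD (0.218), BUB1B (0.203), XPC (0.125), HBEGF (0.119), XAF1 (0.109), STC2 (0.0864) and MMP2 (0.0706). The others were LYZ (0.0645), CSF1R (0.0628), SELPLG (0.0598), MDM2 (0.0596), SPI1 (0.0589), ITGA2B (0.0584), S100A8 (0.0551), JDP2 (0.0547), FAS (0.0537), STARD4 (0.053), ANGPT1 (0.052), PMAIP1 (0.0507) and KRT8 (0.0504). With a per-library trend of expression on GC content removed, an alternative chosen after seeing the data, 1221 genes were higher and 1568 lower (43.8% higher against 53.9%). In that fit VASH1 (0.0684), ANGPT1 (0.0976), LSS (0.061), MVD (0.0939), XAF1 (0.0555) and SPI1 (0.162) lost their calls. The balance also turned with a transcript length trend removed, likewise chosen after seeing the data (1307 higher and 1603 lower). It turned with upper-quartile factors too (1314 and 1410), so the turn is not particular to GC content. In a principal component analysis of log2 CPM the first component held 42.1% of the variance, and wild-type replicate 2 lay at -13.5, nearer to the knockout libraries (21.0 to 35.5) than wild-type replicates 1 (-37.9) and 3 (-34.9).

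**Figure D1:**
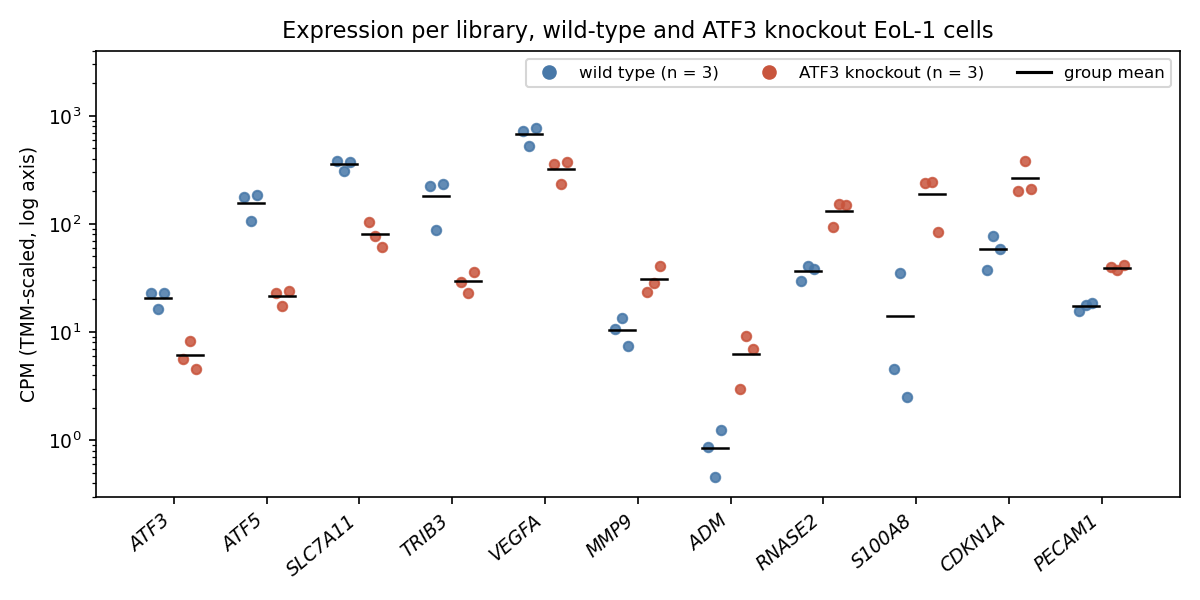
Expression of 11 genes in each library, as TMM-scaled CPM on a log axis, with wild-type libraries in blue, ATF3 knockout libraries in red, 1 point per library (n = 3 per group) and the group mean as a black bar. ATF3, ATF5, SLC7A11, TRIB3 and VEGFA were lower in all 3 knockout libraries, and MMP9, ADM, RNASE2, S100A8, CDKN1A and PECAM1 were higher in all 3.

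Of the 6 largest rises under the naming rule, the myeloid and immune genes S100A8 and IL7R were the most abundant. S100A8, a subunit of calprotectin (chromosome 1, 153390032 to 153391188), stood at 13.98 ± 18.2 CPM in wild type and 189 ± 91.4 CPM in knockout (log2 fold change 3.75, SE 0.97, edgeR adjusted p = 0.037). IL7R, the interleukin-7 receptor alpha chain (chromosome 5, 35852695 to 35879603), went from 6.32 ± 7.15 to 71.3 ± 28.7 CPM (3.49, SE 0.76, adjusted p = 0.0227). Wild-type replicate 2 held 35.0 CPM of S100A8 and 14.6 CPM of IL7R, against 4.51 and 1.98 in wild-type replicate 1, and without it the log2 fold changes were 5.75 and 5.02. S100A8 lost its call without wild-type replicate 3 (3.26, adjusted p = 0.0927), knockout replicate 1 (0.0905) or knockout replicate 2 (0.0856), and so did IL7R without these libraries (3.10 with 0.0791, 0.0635 and 0.0526). The small GTPase RAB7B rose by 4.04 (SE 1.00), with 13.9 CPM in knockout replicate 3 against 2.15 and 2.95 in knockout replicates 1 and 2, and without knockout replicate 3 the rise was 2.72 and its adjusted p went from 0.0325 to 0.0515. RAB7B also lost its call without wild-type replicate 2 (0.0595) or 3 (0.105), and with limma-voom (0.0653). The beta-defensin gene DEFB1 rose by 5.30 (SE 0.62, to 2.54 ± 1.43 CPM) and the lipid phosphatase gene PLPP1 by 4.82 (SE 0.58, 0.156 to 4.51 CPM). PLPP1 shares 481 exon bases with MTREX on the opposite strand. VARS2, the mitochondrial valyl-tRNA synthetase (chromosome 6, 30908242 to 30926459), had 0, 0 and 5 reads in wild type and 118, 82 and 163 in knockout (log2 fold change 6.08, SE 0.82), and 63.1, 81.8 and 163 of the knockout reads were assigned to the transcript ENST00000625423.2, which had 0 reads in each wild-type library. Its log2 fold change was 9.92 without wild-type replicate 3, the sole wild-type library with any read. The wild-type libraries left in that fit had 0 reads of VARS2, so the size of that value is not measured. VARS2 shares 1858 exon bases on the same strand with GTF2H4, which had 0 reads in every library. Adding 5 transcripts that matched no gene and equal a VARS2 transcript in length gave a log2 ratio of mean CPM of 5.39. Those transcripts held 0.061 CPM in wild type and 0.718 CPM in knockout. A match by length misses copies of other lengths, so whether wild-type reads of VARS2 were assigned elsewhere is not settled.

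Among the 6 largest falls, CBS, the enzyme that forms cystathionine from homocysteine (chromosome 21, 43053191 to 43076943), fell by 4.68 (SE 0.94, adjusted p = 0.0188), from 3.56 ± 3.43 to 0.137 ± 0.0985 CPM. Wild-type replicate 3 held 7.47 CPM of CBS against 2.16 and 1.05 in wild-type replicates 1 and 2, and without it the log2 fold change was -3.54 (adjusted p = 0.051). Without knockout replicate 1 it was -5.26 (adjusted p = 0.0508). The secreted glycoprotein gene STC2 fell by 4.22 (SE 0.79), and its log2 fold change was -3.54 without wild-type replicate 3 (adjusted p = 0.0544) and -4.85 without knockout replicate 3. The zinc finger repressor gene TRPS1 fell by 3.28 (SE 0.44, 1.81 to 0.184 CPM). The potassium channel gene KCNK17 fell by 2.99 (SE 0.45, 1.67 to 0.207 CPM), with a log2 fold change of -3.67 without knockout replicate 2. ZFP91-CNTF, a read-through gene, had 39, 21 and 26 reads in wild type and 0 in every knockout library, a level at least 28.4-fold lower with 3 reads over the 3 knockout libraries together as the limit of a count of 0. It shares 1685 exon bases with ZFP91, and the sum of both genes differed by -0.15 on the log2 scale. ADAM32 fell by 3.68 (SE 0.73, adjusted p = 0.0185), from 1.29 to 0.0963 CPM. However, with effective length as an offset its log2 fold change was -0.51 with an adjusted p of 0.69.

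The angiogenic factors moved in both directions. Of 21 tested genes on the list of pro-angiogenic factors, 5 rose and 2 fell over all genes tested, and 8 rose and 2 fell adjusted over the list alone. MMP9, a secreted gelatinase (chromosome 20, 46008908 to 46016561), rose from 10.5 ± 3.03 to 30.8 ± 8.68 CPM (log2 fold change 1.55, SE 0.27, edgeR adjusted p = 0.0133). ADM, which encodes the vasodilator peptide adrenomedullin, rose by 2.89 (SE 0.51, 0.854 to 6.33 CPM), and GRN, which encodes progranulin, by 0.68 (SE 0.13, 162 to 261 CPM). Outside the naming rule, and chosen after their values were seen, are the other called members. VEGFA, the main endothelial growth factor gene, (chromosome 6, 43770184 to 43786487) fell by 1.06 (SE 0.21, adjusted p = 0.0176), from 674 ± 128 to 322 ± 75.6 CPM, and ANGPT1, a ligand of the endothelial receptor TEK, fell by 1.02 (adjusted p = 0.025). HBEGF rose by 0.58 and MMP2 by 0.80, and neither passed with the effective length offset (adjusted p = 0.119 and 0.0706). ANGPT1 did not pass with that offset either (adjusted p = 0.052), nor with the GC trend removed. The list as a whole did not pass camera (adjusted p = 0.0723), but it did without wild-type replicate 1 (adjusted p = 0.0446), with the effective length offset (0.0301) and with a transcript length trend removed (0.0481). Of 8 tested anti-angiogenic factors, VASH1, an inhibitor made by endothelial cells, alone rose, by 0.46 (SE 0.11, adjusted p = 0.0302), also adjusted over the list alone, and the list did not pass (camera adjusted p = 0.561).

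The integrated stress response list had the largest share of lowered genes of the 23 lists. Of its 26 tested members, which include transcription factors, amino acid transporters and enzymes of serine and asparagine synthesis, 23 fell and none rose, over all genes and adjusted over the list alone. The median log2 fold change was -1.05 (camera adjusted p = 8.07e-13). That call was lost with an estimated correlation, at 0.616 between the genes (adjusted p = 0.476 with an estimated correlation). ATF5, a transcription factor of this response (chromosome 19, 49928702 to 49933935), fell by 2.87 (SE 0.23, edgeR adjusted p = 0.00731), from 157 ± 43.0 to 21.4 ± 3.32 CPM. The subunits of the amino acid exchanger SLC7A5 (chromosome 16, 87830023 to 87869488) and SLC3A2 fell by 1.25 (SE 0.10) and by 0.84 (SE 0.08), and SLC7A5 went from 2127 ± 254 to 893 ± 68.2 CPM. Chosen after their values were seen, the pseudokinase gene TRIB3 fell by 2.63, the cystine transporter gene SLC7A11 fell by 2.13, DDIT3 fell by 1.51, the asparagine synthetase gene ASNS fell by 1.09 and ATF4 fell by 0.54. ATF5 shares 626 exon bases with NUP62 and DDIT3 shares 355 with MARS1, both on the opposite strand. Over all libraries NUP62 held 38847 reads against 14814 of ATF5, and MARS1 held 70939 against 2953 of DDIT3. MARS1 was itself called lower, so shared reads are not excluded as part of the fall of DDIT3.

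**Figure D2:**
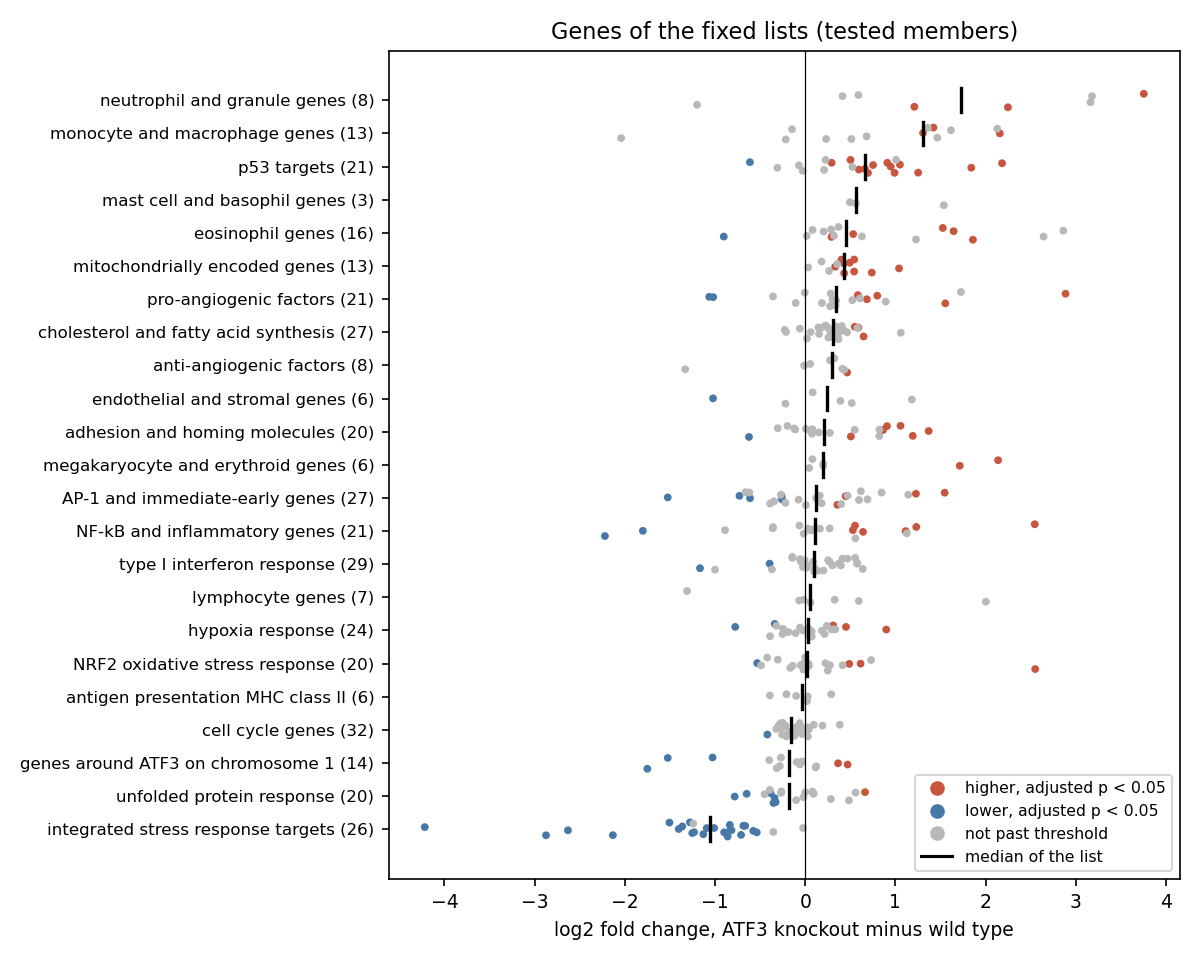
Log2 fold change (knockout minus wild type, horizontal axis) of every tested gene on the 23 fixed lists, with 1 point per gene, the number of tested genes in brackets, and the list median as a black bar. Red points were higher and blue points lower at an edgeR adjusted p of 0.05, and grey points did not pass. The integrated stress response list has 23 blue points among 26, and the p53 list 13 red and 1 blue among 21.

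The list of the unfolded protein response, which acts on protein folding in the endoplasmic reticulum, did not pass (camera adjusted p = 0.233). Of 20 tested genes, 6 fell and 1 rose (8 and 3 adjusted over the list alone). SEL1L, part of the degradation machinery of the endoplasmic reticulum, fell by 0.78 (SE 0.12), the chaperone gene HSPA5 fell by 0.35 (SE 0.08), and the lectin chaperone gene CALR rose by 0.66 (SE 0.14). Of 24 hypoxia response genes 3 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.924). PFKFB4, a regulator of glycolysis, rose by 0.90 (SE 0.08), and PDK1 and HK2, which act on glucose use, fell by 0.78 (SE 0.09) and by 0.34 (SE 0.07). Of 20 genes of the NRF2 oxidative stress response 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.569). The haem oxygenase gene HMOX1 rose by 2.55 (SE 0.39, 0.204 to 1.21 CPM), and TALDO1 of the pentose phosphate pathway rose by 0.49 (SE 0.10).

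Targets of the tumour suppressor p53 were mostly higher in knockout. Of 21 tested, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.66 (camera adjusted p = 0.000783, and adjusted p = 0.554 with an estimated correlation). CDKN1A, an inhibitor of cyclin-dependent kinases (chromosome 6, 36676460 to 36687339), rose from 58.1 ± 20.3 to 264 ± 99.1 CPM (2.18, SE 0.34, edgeR adjusted p = 0.011). DDB2 and XPC, which recognise damaged DNA, rose by 0.75 (SE 0.11) and 0.59 (SE 0.10), though XPC did not pass with the effective length offset (adjusted p = 0.125). Chosen after their values were seen, the p53 ligase gene MDM2 rose by 0.91 and the death receptor gene FAS by 1.05, and the apoptosis gene PMAIP1 fell by 0.61. FAS shares 380 exon bases with ACTA2, XPC shares 318 with LSM3, and MDM2 shares 439 with a processed pseudogene. Of 32 cell cycle genes 2 fell and none rose, also adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.0119, and adjusted p = 0.739 with an estimated correlation). These were MCM6, a subunit of the replicative helicase, which fell by 0.42 (SE 0.07), and the spindle checkpoint gene BUB1B, which fell by 0.29 (SE 0.05) and did not pass with the effective length offset (adjusted p = 0.203). The cell cycle call also ended without knockout replicate 1 (adjusted p = 0.149).

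The tested eosinophil genes were higher in knockout as a list by camera at its preset correlation. The list holds 27 genes, of which 16 passed the low-count filter and were tested. EPX, PRG2, CLC, SIGLEC8, CCR3 and IL5RA were among those not tested. Of 16 tested eosinophil genes 5 rose and 1 fell, also adjusted over the list alone, with a median log2 fold change of 0.45 (camera adjusted p = 0.00536, and adjusted p = 0.448 with an estimated correlation). RNASE2, the eosinophil-derived neurotoxin (chromosome 14, 20955452 to 20956436), rose from 36.3 ± 6.10 to 132 ± 33.4 CPM (1.86, SE 0.22, edgeR adjusted p = 0.0081). Its paralog RNASE3, the eosinophil cationic protein (20891399 to 20892348), rose by 1.65 (SE 0.19), with 8.69 ± 1.94 against 27.2 ± 4.11 CPM. ADGRE1, an adhesion G protein-coupled receptor, rose by 1.52 (SE 0.23) at 0.646 against 1.87 CPM. Chosen after their values were seen, the myeloid transcription factor genes CEBPA and SPI1 rose by 0.53 and 0.29, and CEBPB fell by 0.90.

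Some markers of other myeloid cells also rose. The neutrophil and granule list holds 21 genes, of which 8 were tested. Of these 8, 3 rose over all genes (5 rose and 1 fell adjusted over the list alone), with a median of 1.73 (camera adjusted p = 0.0428, and adjusted p = 0.448 with an estimated correlation). Besides S100A8, the early granulocyte gene MS4A3 rose by 2.25 (SE 0.34, 5.61 to 26.6 CPM) and the myeloperoxidase gene MPO by 1.21 (SE 0.22, 51.8 to 120 CPM). The granule protease gene CTSG had a log2 fold change of -1.20 (SE 0.39, adjusted p = 0.0679) and the granule protein gene BPI 0.41 (adjusted p = 0.644). Both were chosen after their values were seen. The call of this list ended without wild-type replicate 3 (adjusted p = 0.0547), knockout replicate 1 (0.0757) or knockout replicate 3 (0.0841). Of 13 monocyte and macrophage genes 3 rose and none fell (4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0867), though it did without wild-type replicate 2 (0.0171) or without the low-count filter (0.0163). These were the transcription factor gene IRF8 at 1.31 (SE 0.22), the CSF1 receptor gene CSF1R at 1.42 (SE 0.37) and the lysozyme gene LYZ at 2.16 (SE 0.61). Wild-type replicate 2 held 259 CPM of LYZ and 78.2 CPM of CSF1R, against 65.6 and 28.4 in wild-type replicate 1 and 62.3 and 39.5 in wild-type replicate 3. Without wild-type replicate 2 the log2 fold change of LYZ was 3.17. That library also held the most S100A8, MS4A3, MPO and IRF8 of the wild-type libraries, with 8.33 CPM of MS4A3 against 3.39 and 5.10 in wild-type replicates 1 and 3. These markers thus also differed within the wild-type group, with that library nearest to the knockout levels. LYZ lost its call without wild-type replicate 3 (1.82, adjusted p = 0.132), knockout replicate 1 (0.109) or knockout replicate 2 (0.114). CSF1R lost its call without wild-type replicate 3 (1.29, adjusted p = 0.126) or knockout replicate 1 (0.0865), 2 (0.0588) or 3 (0.0748). Of 6 megakaryocyte and erythroid genes NFE2, a bZIP factor of platelet formation, rose by 2.14 (SE 0.16, 18.6 to 82.0 CPM) and ITGA2B by 1.71 (SE 0.37), both also adjusted over the list alone (camera adjusted p = 0.0867). This list passed without knockout replicate 1 (0.0452) and with the effective length offset (0.0301).

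The lists of lymphocyte, mast cell and basophil, and endothelial and stromal markers did not pass. None of 7 lymphocyte genes passed, over all genes or adjusted over the list alone (camera adjusted p = 0.689), and the most abundant, NKG7, stood at 117 ± 10.2 against 147 ± 20.8 CPM (adjusted p = 0.09, 0.0485 with the DESeq2 Wald test and 0.0436 without knockout replicate 2). None of 3 mast cell and basophil genes passed over all genes, MITF alone was higher adjusted over the list alone (camera adjusted p = 0.376), and it stood at 8.92 ± 0.240 against 12.6 ± 2.05 CPM (adjusted p = 0.0525). MITF passed as higher with the DESeq2 Wald test (0.0252), a mean of at least 1 CPM (0.0487), the GC (0.0218) or length (0.0489) trend removed, and without knockout replicate 3 (0.0212). Of 6 endothelial and stromal genes the keratin gene KRT8 fell by 1.02 (SE 0.23, 5.57 to 2.74 CPM), also adjusted over the list alone (camera adjusted p = 0.919).

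Called AP-1 and immediate-early genes went in both directions. Of 27 tested 4 rose and 5 fell (5 and 5 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.845). FOS rose by 1.23 (SE 0.21, 8.48 to 19.9 CPM) and ZFP36, which destabilises cytokine mRNAs, rose by 0.45 (SE 0.08), while JDP2, a bZIP repressor, fell by 0.61 (SE 0.12). Of 21 NF-kB and inflammatory genes 6 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.325). TNFAIP3 and TNFAIP2, both induced by tumour necrosis factor, rose by 1.11 (SE 0.14) and 1.23 (SE 0.16). The monocyte chemokine gene CCL2 fell by 1.80 (SE 0.35), from 92.6 ± 12.3 to 26.6 ± 14.6 CPM. Of 29 type I interferon response genes RSAD2 fell by 1.17 (SE 0.27) and XAF1 by 0.40 (SE 0.10, adjusted p = 0.109 with the effective length offset), but none passed adjusted over the list alone (camera adjusted p = 0.727). The list of antigen presentation by MHC class II holds 16 genes, of which 6 were tested. HLA-DRB1 and HLA-DRB5 were the only HLA genes among these, so most class II genes were not assessed. None of the 6 passed by either adjustment (camera adjusted p = 0.919), and CD74 stood at 664 ± 147 against 672 ± 178 CPM.

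Adhesion molecules included some of the smallest p-values. Of 20 tested 6 rose and 1 fell (7 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0786) except without wild-type replicate 1 (0.0446) or knockout replicate 2 (0.033). PECAM1, an adhesion molecule of leukocytes and endothelium (chromosome 17, 64319415 to 64413776), rose from 17.3 ± 1.59 to 39.4 ± 2.18 CPM (1.19, SE 0.09, edgeR adjusted p = 0.00731). The integrin genes ITGAM and ITGA5 rose by 1.37 (SE 0.18) and 0.51 (SE 0.07). SELPLG, the ligand of P-selectin, was the member that fell, by 0.62, and was chosen after its values were seen.

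Transcripts of the mitochondrial genome were higher in knockout. Of the 13 protein-coding genes 9 rose and none fell (11 adjusted over the list alone), with a median of 0.43 (camera adjusted p = 9.64e-05, and adjusted p = 0.55 with an estimated correlation). MT-CO1 and MT-CO2, subunits of cytochrome c oxidase, each rose by 0.54 (SE 0.08), and MT-ND5, a subunit of complex I, by 0.74 (SE 0.11). Mitochondrial genes took 3.72% ± 0.113 (SD, n = 3) of the gene reads in wild type and 5.20% ± 0.580 (SD, n = 3) in knockout (exact two-sided permutation p = 0.1, the smallest possible). Of 27 genes of cholesterol and fatty acid synthesis 3 rose and none fell, with a median of 0.30 (camera adjusted p = 0.0175, and adjusted p = 0.739 with an estimated correlation), and none passed adjusted over the list alone. LSS and MVD, enzymes of sterol synthesis, rose by 0.59 (SE 0.14) and 0.55 (SE 0.15, adjusted p = 0.218 for MVD with the effective length offset), and the sterol transport gene STARD4 by 0.65 (SE 0.16). The call of that list ended without wild-type replicate 2 (adjusted p = 0.0828) or knockout replicate 3 (0.203).

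Close to ATF3 on chromosome 1, BATF3 and TATDN3 also fell. Of 14 tested genes in this region, ATF3 included, 3 fell and 2 rose over all genes, and 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.0867, 0.0446 without wild-type replicate 1 and 0.0385 with the effective length offset). BATF3, a bZIP factor (212686418 to 212699985), fell by 1.52 (SE 0.35, edgeR adjusted p = 0.0259), from 9.05 ± 2.73 to 3.14 ± 1.21 CPM. TATDN3, a putative deoxyribonuclease gene (212791828 to 212816626), fell by 1.03 (SE 0.12, adjusted p = 0.0081), from 29.4 ± 4.49 to 14.4 ± 0.313 CPM. NSL1, which lies between them (212726153 to 212791782) and was chosen after its values were seen, had a log2 fold change of -0.32 (SE 0.09, adjusted p = 0.0524). NSL1 passed as lower with DESeq2 size factors (0.0495), upper-quartile factors (0.0434), the DESeq2 Wald test (0.0233), a mean of at least 1 CPM (0.0491), protein-coding genes alone (0.0481) and without wild-type replicate 2 (-0.40, 0.0244).

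**Figure D3:**
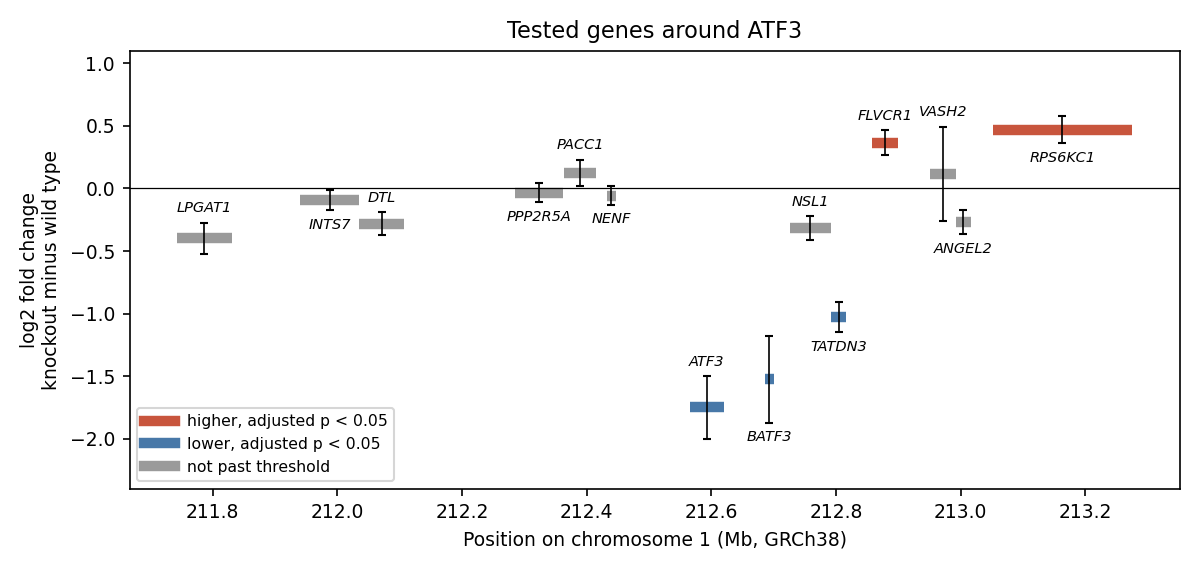
Log2 fold change (knockout minus wild type) of the 14 tested genes around ATF3 against their position on chromosome 1 in megabases (GRCh38). Each bar spans a gene, the error bar is 1 SE, blue bars were lower, red bars higher at an edgeR adjusted p of 0.05, and grey bars did not pass. ATF3 (-1.75), BATF3 (-1.52) and TATDN3 (-1.03) lie below the other genes.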

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

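The counts over splits of the libraries were planned. The tests of culture state, of whole-chromosome gain or loss, of NSL1 against TATDN3 and of transcripts without a gene, the removal of GC and length trends, and the GC values without a library, were chosen after results had been seen.

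Transcripts outside the gene tests gave 1 call, close to the threshold. Of 1913 tested transcripts that matched no gene in the annotation, 1 was higher in knockout and 0 were lower by edgeR, and 198 had an unadjusted p under 0.05. The transcript was ENST00000655421.1, with 0 reads in every wild-type library and 340, 313 and 399 in knockout replicates 1, 2 and 3 (adjusted p = 0.0491). Switches of this form were common: 109 transcripts stood at 0 in wild type alone with at least 20 reads in each knockout library, and 109 the other way round, while the 18 mixed trios of libraries gave 55 to 80.

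The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10 with a result as large for each count, called 2770 genes, against 2 in the highest other split. Those 2 genes lay in the same direction, and since the groups of such a split have no order, 2 is set against both the 1494 higher and the 1276 lower genes of the real split. The real split called 7 gene lists, against 6.

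The fall of the integrated stress response list was weighed against trends between libraries and against the state of the cultures. Removing the per-library GC trend left the median log2 fold change at -1.04 and removing the length trend left it at -1.11, against -1.05 without removal, so neither trend accounts for the fall. The mean log2 CPM of the list was 7.28, 6.91 and 7.03 in wild type and 6.11, 5.76 and 5.86 in knockout, with no overlap and an exact permutation p of 0.1, the smallest possible. Differences in medium, density or amino acid supply between the cultures of the groups could give the same values and cannot be told apart from the knockout, because the labels do not say whether the groups were grown side by side. The loss of ATF3 remains a hypothesis open beside it.

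Fold changes also followed base composition. The median log2 fold change went from -0.13 in the fifth of genes with the lowest GC content to 0.15 in the fifth with the highest, with Spearman's rho 0.256 across genes, which are not independent replicates. Knockout replicate 3 carried more of this trend than the other libraries, and without it the medians went from -0.07 to 0.11 with a rho of 0.151. Removing the GC trend lowered the spread of the autosome medians to 0.476 of its value, consistent with a GC trend behind part of the differences between chromosomes. That ratio was 0.629 without knockout replicate 3 and 0.378 to 0.513 without any other library, so how far the trend accounts for these differences stays open. A chromosome gained or lost in every cell of a knockout library would move its genes by more than was seen. The largest autosome median was 0.177 in size (chromosome 4, knockout replicate 3). A gain or loss in part of the cells could give a shift of that size and is not excluded. Whether the GC trend came from library preparation or from the cells cannot be told from these values.

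BATF3 and TATDN3 fell beside ATF3, and loss of the DNA segment from ATF3 to TATDN3 in the knockout cells could lower all genes within it. NSL1 lies inside that segment, and its log2 fold change was higher than that of TATDN3 by 0.711 (SE 0.153), which argues against loss of the whole segment as the cause of the fall of TATDN3. NSL1 itself passed as lower in 6 alternatives, so a smaller fall of NSL1 is not ruled out. Chance location, smaller edits near the target and an effect of ATF3 on its neighbours stay open and were not tested.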

How the results depend on the processing

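The trend removals and the limma-voom and DESeq2 fits without wild-type replicate 1 were chosen after seeing the data. Outside the edgeR fits without a library, the counts of genes stayed within 1.5 times the main ones except in these cases. With the effective length offset 722 genes were higher and 661 lower, with limma-voom without wild-type replicate 1 0 were higher and 5 lower, and tested against a 1.5-fold change 10 were higher and 7 lower, which the stricter test explains by construction. For the other cases the cause was not tested. Over the edgeR fits without a library the higher genes ranged from 0 to 1370 and the lower from 0 to 1388. Both counts were lowest without wild-type replicate 1 and highest without knockout replicate 3. The log2 fold change of ATF3 ranged from -2.03 to -1.58, with a highest adjusted p of 0.0527, and the lists called from 5 to 10. In all alternatives with a value ATF3 stayed lower.

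With the effective length offset 17 of the 2770 called genes changed sign, none of which passed there, and in the other fits none did. Beyond these, signs changed for CD74 and for lists that did not pass in the fits concerned, and the cause was not tested. For lists the values are the mean log2 fold change less that of the other genes, while the direction was judged by camera, which weighs genes by their variance, so the sign of a mean and the direction can part. The fold change of CD74 was -0.002 with upper-quartile factors, -0.13 with the GC trend removed and -0.014 with the length trend removed, and ranged from -0.10 to 0.22 without a library. The direction changed without a low-count filter for hypoxia (-0.082), MHC class II (0.22), mast cell and basophil genes (-0.36) and endothelial and stromal genes (-0.10). The hypoxia mean was -0.058 with the effective length offset and -0.034 with either trend removed, the AP-1 mean was -0.010 with the GC trend removed, and the endothelial and stromal mean was 0.044 with the filter at a mean of 1 CPM. Without a library, the means ranged from -0.059 to 0.017 for hypoxia, -0.27 to 0.12 for MHC class II, -0.35 to 0.20 for endothelial and stromal genes and -0.18 to 0.44 for type I interferon genes. Some means changed sign with the camera direction kept. The anti-angiogenic mean was -0.015 with limma-voom, -0.024 without a low-count filter, -0.009 with the filter at a mean of 1 CPM and -0.025 with the replicate block, and ranged from -0.33 to 0.26 without a library. The lymphocyte mean was -0.28 with the filter at a mean of 1 CPM and -0.11 for protein-coding genes alone, and ranged from -0.048 to 0.51 without a library. The NRF2 mean was -0.002 with the filter at a mean of 1 CPM, and the megakaryocyte and erythroid mean -0.11 without a low-count filter.

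The replicate block called 1225 higher and 1093 lower genes and 7 lists, with ATF3 at -1.77. In it 6 genes of the report lay just over the threshold, VASH1 (adjusted p = 0.0575), RSAD2 (0.055), MVD (0.0586), KRT8 (0.0516), SPI1 (0.0527) and MMP2 (0.0677). Libraries with the same number shared little: the correlations of their deviations were -0.092, 0.106 and 0.196, and not every library correlated best with its own number, so the numbers were not taken as pairs. Depth was similar between libraries, and the median SE of the log2 fold change was 0.38 for genes under 1 CPM, 0.24 from 1 to 10 CPM, 0.10 from 10 to 100 CPM and 0.076 above, though single abundant genes such as S100A8 (SE 0.97) had wide errors.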

Other observations

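The gene families in this part, and their tests, were chosen after the data were seen. Several families of genes of protein synthesis, mostly outside the fixed lists, were among them. Of 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 14 fell and none rose, with a median log2 fold change of -0.57 (camera adjusted p = 6.91e-06, and adjusted p = 0.207 with an estimated correlation). WARS1, GARS1 and CARS1 of this family are also on the integrated stress response list. Of 17 mitochondrial synthetases 2 rose and 1 fell (camera adjusted p = 0.762). Of 80 cytosolic ribosomal protein genes 30 fell and none rose, with a median of -0.25 (camera adjusted p = 9.52e-11, and adjusted p = 0.445 with an estimated correlation). Of 54 translation initiation factors 17 fell and 5 rose (camera adjusted p = 0.00462, and adjusted p = 0.207 with an estimated correlation). Of 26 subunits of the RNA exosome and of RNA polymerases I and III, 9 fell and none rose (camera adjusted p = 4.82e-05, and adjusted p = 0.207 with an estimated correlation). The medians of these families kept their sign with DESeq2 size factors, with upper-quartile factors and with the GC trend removed.

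Amino acid transporters of the SLC1A, SLC7A and SLC38A families were called in both directions, with 7 lower and 2 higher among 17 (camera adjusted p = 0.0476, and adjusted p = 0.207 with an estimated correlation). Subunits of the lysosomal proton pump were higher for 6 genes and lower for 2 among 18 (camera adjusted p = 0.0265, and adjusted p = 0.207 with an estimated correlation). Of 37 complex I subunits encoded in the nucleus 2 were higher and 2 lower (camera adjusted p = 0.919). Zinc finger genes, with 33 higher and 31 lower among 406, did not pass (camera adjusted p = 0.894). The families not described above were mitochondrial ribosomal proteins (13 lower, 2 higher, camera adjusted p = 0.0139) and nucleolar ribosome assembly factors (11 lower, 3 higher, 0.00183). Proteasome subunits (4 lower, 2 higher, camera adjusted p = 0.196) and cathepsins (0 lower, 2 higher, 0.603) did not pass. In all, 13 families were tested, 8 passed camera at the preset correlation, and none passed with an estimated correlation.

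PRPF8, a core protein of the spliceosome, had a log2 fold change of 2.12 (SE 0.14, edgeR adjusted p = 0.00731), chosen here after its values were seen. Its transcript ENST00000304992.11 had 0 reads in every wild-type library and 570.0, 564 and 347 in knockout, while ENST00000573725.1 held 140, 177 and 148 reads in wild type and 148, 102 and 118 in knockout. With the effective length offset the log2 fold change of PRPF8 was 1.08 with an adjusted p of 0.228. Adding 4 transcripts that matched no gene and equal a PRPF8 transcript in length gave a log2 ratio of mean CPM of 1.81. ENST00000304992.11 has the form of the switches between transcripts counted above, and a match by length misses copies of other lengths. Whether wild-type reads of PRPF8 were assigned elsewhere is therefore not settled. CENPU, a centromere protein gene chosen after its values were seen, had the smallest adjusted p of all genes, 0.00613, and fell by 1.14 (SE 0.06), from 93.4 ± 1.36 to 42.3 ± 2.21 CPM (SD, n = 3).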
